A study of Mus musculus with 22 samples.

How the data were processed

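Poly(A) RNA from the livers of male C57BL/6 mice was sequenced in 22 libraries of 5 groups, JAX (n = 4), TAC (n = 4), GF (n = 4), GF_JAX (n = 5) and GF_TAC (n = 5). Per the labels, total RNA was isolated with Trizol, mRNA was captured on poly(A) beads (NEBNext) and libraries were made with a ThruPLEX kit. The labels number the libraries within each group but do not state that each came from a separate animal, so p-values measure the spread between these samples, which may be technical in part.

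The values are RPKM computed by the authors, in 1 table of genes by libraries. Per the submitters' processing notes, Bowtie 1.0.0, Cuffdiff 2.1.1 and the genome build mm9 were used. The roles of these tools, the gene annotation, read filters, duplicate removal and any scaling between libraries are not given in the sources. The table held 24397 gene entries. Left out were 461 empty entries at its end (304 of them without a last value) and 27 entries whose gene names a spreadsheet had turned into date numbers and which cannot be assigned to a gene. The other 23909 carried symbols, and 6546 of those were at 0 in every library. An exact 0 may be a failed estimate and is reported as listed at 0.

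RPKM carry no counts, so no count test was used. Depth was read from the low values: of 3337 genes whose highest depth-scaled RPKM was at most 2, 2820 (84.5%) held whole multiples of 1 read in every library, within 0.02 reads, against 0% after random rescaling. The steps gave each library's depth relative to JAX 1, and with transcript lengths (2375 genes) a median of 2.29 M counted reads for JAX 1 (quartiles 2.08 and 2.38) and 1.35 to 3.79 M per library. Sum, depth and spread between libraries set the precision. At 2 M reads a gene of 1 kb at 1 RPKM rests on about 2 reads. Transcript lengths were those of the longest protein-coding isoform in GENCODE M21 and matched 11169 of 12264 tested genes (91.1%) by symbol. That annotation belongs to another build than the deposited values, and no coordinates were used. A library's length slope is that of log2 RPKM on log2 length over 7530 genes with a mean RPKM of 5 to 300.

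Values were analysed as log2(RPKM + 1), with a pseudocount of 1. Genes with an RPKM of at least 1 in at least 4 libraries, the smallest group size, were tested (12264). A single linear model over all libraries and groups was fitted with limma 3.58.1 (trend) in R 4.3.3, without covariates, so that the groups share one estimate of spread per gene. This assumes that the groups vary alike. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. All adjusted p of genes are from limma. The comparisons were TAC minus JAX, GF_TAC minus GF_JAX, GF_JAX minus GF, GF_TAC minus GF, GF minus JAX, GF minus TAC, and the interaction, which is the donor difference in recipients minus that in vendor mice. The correlation of both donor differences across genes was tested by exact permutation of the 10 recipient libraries. For the colonisation comparisons, which share the GF libraries, unchanged groups were simulated against the same controls. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 served for tables, permutations and figures.

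Gene lists, tests, the rule for named genes and a first series of alternatives were fixed before the data were examined. Lists with at least 5 tested members, 30 of 34, were tested with camera (limma), two-sided, with a preset correlation of 0.01 and again with an estimated one, adjusted over the lists of a comparison. The pathway lists were bile acid synthesis, bile acid transport and FXR targets, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation and PPARa targets, gluconeogenesis, amino acid breakdown and urea cycle, drug metabolism (CAR and PXR targets), AHR targets, NRF2 targets, male-biased and female-biased liver genes, core clock, acute phase, interferon, antigen presentation, ER stress and amino acid response, and cell cycle. Immediate early and heat shock genes, cytosolic ribosomal proteins and the respiratory chain served as signs of RNA quality. Cell type lists covered Kupffer cells, T and NK cells, B and plasma cells, neutrophils, sinusoidal endothelium, stellate cells, cholangiocytes, erythroid cells and adipose tissue. Pancreas, gut epithelium, skeletal muscle and C57BL/6 substrain markers had fewer tested members and are given gene by gene.

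Named genes were, per comparison, the 8 largest increases and the 8 largest decreases among passing genes without overlap of the libraries (predicted genes, clone names and the Mup family left out), up to 4 members with the smallest p of each passing list, up to 2 passing members of each other pathway list, and Cyp7a1, Cyp8b1, Nnt, Wdfy1 and Entpd4 throughout. For the interaction they were the 6 genes with the smallest p. The rule gave 249 genes, of which some are not reported here. Of the list members only a part is printed, chosen after the values were seen, microRNA, snoRNA and pseudogenes are not printed, and 110 genes carry the checks of alternatives and of single libraries. Near-identical, overlapping and antisense genes cannot be told apart, since strand and counting rule are not given.

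The pipeline was tested on simulated counts for the real genes with 200 changed genes and a dispersion of 0.05. It recovered 54% of 2-fold and 97% of 4-fold changes for TAC minus JAX (11023 genes; 5 of 156 calls false), 71.7% and 93% for GF_TAC minus GF_JAX (11021; 12 of 176), 68.7% and 99% for GF_JAX minus GF (11019; 6 of 173), 66% and 94% for GF_TAC minus GF (11043; 9 of 169), 56.2% and 92.9% for GF minus JAX (11021; 2 of 148), and 53% and 98.0% for GF minus TAC (11023; 10 of 160). With the ER stress list raised 1.5-fold in TAC, it alone of 29 lists passed for TAC minus JAX (adjusted p = 2.05e-20, and 2.16e-07 with an estimated correlation, 11169 genes).

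That first series of alternatives comprised pseudocounts of 0.1 and 0.5, no filter, an RPKM minimum of 5, median-ratio scaling, rescaling to a common sum (TPM), quantile normalisation, a fit of only the groups compared, library quality weights, the replicate number as a block, an estimated list correlation and leaving out each library in turn. After the data were seen, 4 more were added: library type (the sign of the length slope) as a term, leaving out GF_JAX 1 and GF_JAX 4, log2 relative depth as a term, and a correction of abundant genes for reads lost at shared start positions, which left out 77 genes above 0.9 of the level that 1 read per start position and strand allows.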

Results

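Liver RNA was sequenced from male C57BL/6 mice in 5 groups. JAX (n = 4) and TAC (n = 4) were conventionally raised mice from the vendors Jackson and Taconic, and GF (n = 4) were germ-free mice, which carry no microbes. GF_JAX (n = 5) and GF_TAC (n = 5) were germ-free mice that received cecal contents of JAX or of TAC mice and were sampled 4 weeks later, after a fast of 16 h. The labels call every animal fasted, but hours are given only for GF_JAX and GF_TAC. The deposited values are RPKM, reads per kilobase of gene scaled to the depth of the library, for 23909 gene symbols, and 12264 genes with an RPKM of at least 1 in at least 4 libraries were tested. Groups are named as in the labels. Differences are on the log2(RPKM + 1) scale, which understates the change of low genes, and errors beside RPKM are SD. Values of genes with near-identical copies (the Cyp2b, Cyp2c, Cyp3a and Ces2 families, Saa1) or with overlapping or antisense partners (Tgoln2, Rsc1a1, Cntf, Dio3os) are uncertain, since reads may have been split between them.

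RPKM summed to between 531282 and 737897 per library. Sequencing depth was read from the low values, which came in steps of 1 read, and lay between 1.35 and 3.79 M counted reads per library. The range was 2.29 to 3.79 M in JAX, 1.87 to 2.45 M in TAC, 1.40 to 3.53 M in GF, 1.35 to 2.85 M in GF_JAX and 2.11 to 3.06 M in GF_TAC. Relative to library JAX 1, mean depth was 1.32 ± 0.276 in JAX (n = 4), 0.956 ± 0.109 in TAC (n = 4), 1.02 ± 0.387 in GF (n = 4), 0.786 ± 0.279 in GF_JAX (n = 5) and 1.12 ± 0.175 in GF_TAC (n = 5). At these depths differences in genes of low RPKM were often not detectable. Pearson r of log2 values lay between 0.933 and 0.978 for libraries of the same group and between 0.932 and 0.978 for libraries of different groups. No pair of libraries agreed within sampling noise (chi-square per degree of freedom of at least 1.76 over 5703 genes).

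The libraries were divided into 2 types by the sign with which RPKM depended on transcript length, a split that the labels do not record. The slope of log2 RPKM on log2 transcript length was positive in 10 libraries, namely all JAX and TAC libraries and GF_JAX 1 and GF_JAX 4 (0.0453 to 0.213), and negative in the other 12 (-0.212 to -0.0309). Every GF library thus had the opposite type to every vendor library, so that for GF against the vendor mice library type and group can be separated only through GF_JAX, which holds both types. The type was also the main axis of the data, with 23.3% of the variance on the first principal component. Albumin (Alb), apolipoprotein A-I (Apoa1) and apolipoprotein E (Apoe), the major secreted liver products, lay at one shared level in each library. Their RPKM fell with depth in step (coefficient of variation 29.0%, 29.6% and 29.9% over 22 libraries, and 2.13%, 1.93% and 1.55% after multiplication by relative depth).

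**Figure D1:**
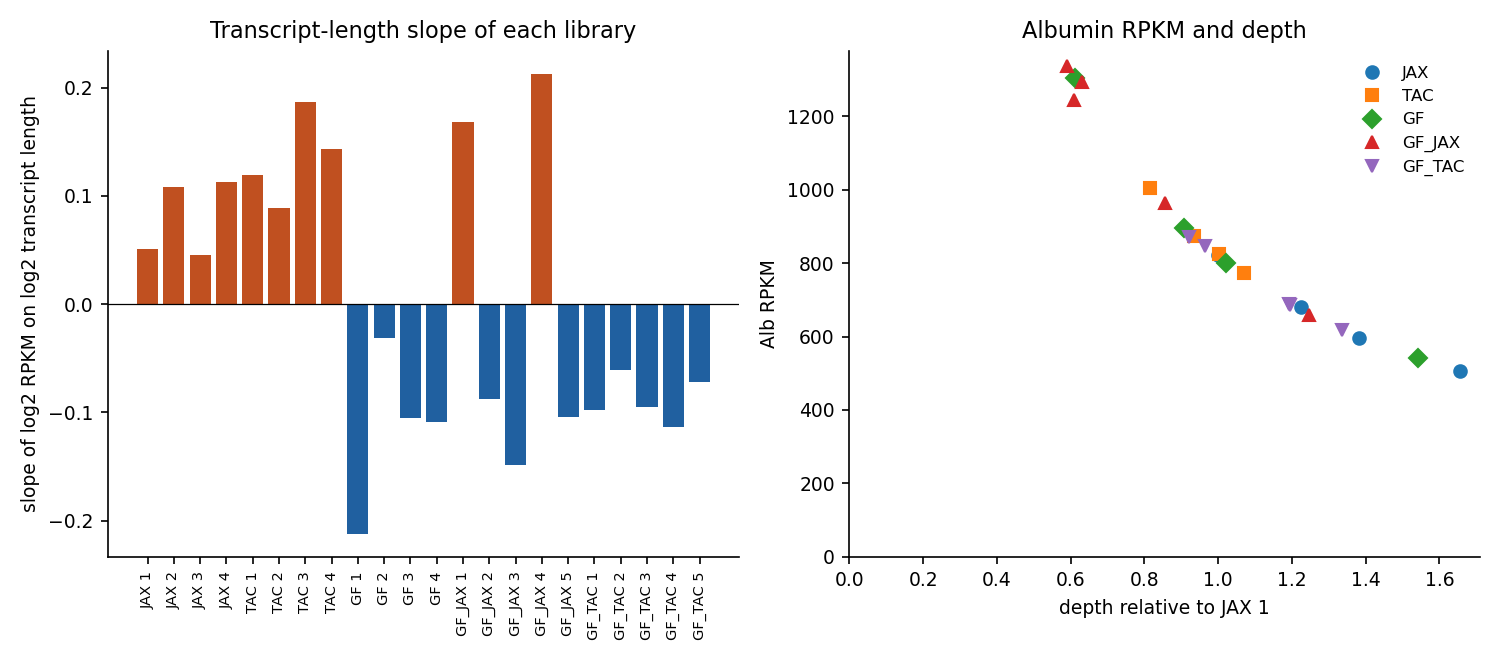
Transcript-length slope of each of the 22 libraries (left; slope of log2 RPKM on log2 transcript length, orange positive, blue negative) and Alb RPKM against depth relative to JAX 1 (right; 1 point per library, marked by group). The 10 libraries with a positive slope are the 8 vendor libraries and GF_JAX 1 and GF_JAX 4, and Alb falls from 1337 to 507 RPKM as depth rises.

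The first comparison asked how livers of conventionally raised TAC mice differed from those of JAX mice. Of 20 genes of the endoplasmic reticulum (ER) stress and amino acid response list 5 rose in TAC (camera adjusted p = 2.22e-18, and adjusted p = 0.0133 with an estimated correlation). Hspa5 (BiP, the main chaperone of the ER) was 1.46-fold higher (409 ± 34.2 against 278 ± 10.8 RPKM, n = 4 and 4, adjusted p = 0.0142). Pdia4, a protein disulfide isomerase, was 1.52-fold higher (200 ± 20.2 against 132 ± 17.99 RPKM, adjusted p = 0.00388). The leptin receptor Lepr was 2.72-fold lower (1.70 ± 0.108 against 6.50 ± 1.71 RPKM, adjusted p = 0.000712). Nnt, a mitochondrial transhydrogenase with a deletion in the C57BL/6J substrain of Jackson, was 1.90-fold higher in TAC (82.2 ± 8.52 against 42.7 ± 1.10 RPKM, adjusted p = 0.00148).

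Among the genes with the largest increases in TAC were Obp2a, an odorant-binding lipocalin (log2 difference 2.55), the acute phase protein Saa1 (2.09), Wdfy1 (1.499), the ubiquitin ligase Mid1 (1.49), the protease inhibitor Serpine2 (1.49), the kinase subunit Camk2b (1.19) and the male-biased gene Selenbp2 (1.11). Their adjusted p ran from 0.000741 (Mid1) to 0.0433 (Obp2a). Saa1 varied widely among the TAC livers (483 ± 388 RPKM against 90.7 ± 18.4 in JAX, n = 4 and 4). Obp2a averaged 16.0 ± 5.07 against 2.06 ± 1.57 RPKM, Wdfy1 23.9 ± 5.85 against 7.74 ± 2.05 and Serpine2 31.3 ± 2.99 against 10.6 ± 1.51. Among the largest decreases were Lepr (-1.44), the DNA repair gene Rad51b (-1.40), the cytochrome P450 Cyp2a22 (-1.18), the innate receptor Tlr12 (-1.08), Pck2, the mitochondrial form of phosphoenolpyruvate carboxykinase (-1.03), Tmem98 (-0.99), Dclk3 (-0.96) and Tmem86a (-0.88). Their adjusted p ran from 8.19e-05 (Tmem98, 24.2 ± 1.84 against 49.1 ± 4.39 RPKM) to 0.0414 (Tlr12). Among 3 genes fixed as markers of C57BL/6 substrains, Nnt and Wdfy1 rose and Entpd4 fell (-0.83; 21.9 ± 0.959 against 40.0 ± 5.64 RPKM, adjusted p = 0.00148).

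Of the 20 ER stress genes 15 did not pass, and 12 rose adjusted over the list alone. Dnajc3 (0.42, adjusted p = 0.00277), Herpud1 (0.71, adjusted p = 0.0234) and Hyou1 (0.91, adjusted p = 0.0236), the last named after its value was seen, passed beside Hspa5 and Pdia4. It was the only list of this comparison to pass both set tests. In the acute phase list 1 of 27 rose (10 adjusted over the list alone), with Saa4 at 0.76 (adjusted p = 0.0963) and Crp at 0.49 (adjusted p = 0.0643). The set test gave adjusted p = 2.01e-16, and adjusted p = 0.0932 with an estimated correlation. In the amino acid breakdown and urea cycle list none of 21 passed (2 higher adjusted over the list alone), with Kmo at 0.28 (adjusted p = 0.251). The set test gave adjusted p = 1.62e-09, and adjusted p = 0.380 with an estimated correlation. In the male-biased list 1 of 17 rose (4 adjusted over the list alone), with Hsd3b5 at 1.25 (adjusted p = 0.293) and Cyp7b1 at 0.83 (adjusted p = 0.102). The set test gave adjusted p = 4.71e-07, and adjusted p = 0.228 with an estimated correlation. In the interferon list 1 of 30 fell, Rtp4 (-0.86, adjusted p = 0.0316; 2 adjusted over the list alone), and Ifit1 stood at -0.76 (adjusted p = 0.178). This set test pointed down, with adjusted p = 5.10e-06, and adjusted p = 0.245 with an estimated correlation.

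Further lists passed the set test upward in TAC with no member past the threshold over all genes. Bile acid synthesis (13 members, 1 adjusted over the list alone) had adjusted p = 0.000479, and adjusted p = 0.585 with an estimated correlation. Gluconeogenesis (13 members, 0 adjusted over the list alone by limma) had adjusted p = 0.00323, and adjusted p = 0.633 with an estimated correlation. Cholesterol synthesis (24 members) and drug metabolism, CAR and PXR targets (27 members) had adjusted p = 0.00342 and 0.00422 and, for both, adjusted p = 0.802 with an estimated correlation. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at -0.38 (40.2 ± 16.6 against 54.5 ± 25.3 RPKM, adjusted p = 0.859) and Cyp8b1, which sets the share of cholic acid, at 0.18 (adjusted p = 0.801). The lists kept as signs of RNA quality moved too. Respiratory chain genes were higher in 30 of 30 members (median 0.16, adjusted p = 0.000146) and ribosomal protein genes in 28 of 30 (median 0.16, adjusted p = 0.000945). Both had adjusted p = 0.802 with an estimated correlation and no member passing singly, and relative depth was lower in TAC than in JAX. With depth as a term in the fit the CAR and PXR, ribosomal and respiratory lists turned downward (adjusted p = 0.907, 0.000117 and 0.0149), and bile acid synthesis (0.301), cholesterol synthesis (0.268) and gluconeogenesis (0.266) lost the call. Quality weights ended that of cholesterol synthesis (0.0598) and the correction for shared start positions those of the ribosomal (0.335) and respiratory lists (0.188). Calls were also lost without JAX 2 (gluconeogenesis and CAR and PXR 0.0644, ribosomal 0.3004, respiratory 0.0717) and without TAC 2 (cholesterol 0.862, CAR and PXR 0.0628, ribosomal 0.0568). The other 19 lists tested did not pass (adjusted p from 0.0515 for Kupffer cells and macrophages to 0.997). Among these were female-biased genes (0.127), cholangiocytes (0.260), stellate cells and fibroblasts (0.411), core clock (0.428), bile acid transport and FXR targets (0.428), cell cycle (0.461), NRF2 targets (0.672) and AHR targets (0.672). Erythroid cells, adipose tissue, fatty acid synthesis, sinusoidal endothelial cells and neutrophils stood at 0.983, and fatty acid oxidation and PPARa targets, antigen presentation, immediate early and heat shock genes, B and plasma cells, and T and NK cells at 0.997.

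In all, 36 of 12264 genes passed between TAC and JAX, 22 higher and 14 lower, and in all 36 the libraries of the groups did not overlap; over all genes tested this held for 8.22%, against 2.86% by chance. The split was 17 higher and 20 lower after rescaling to a common sum (TPM). The count was 62 with GF_JAX 1 and GF_JAX 4 left out of the shared fit, 69 with library type as a term and 218 with library quality weights. It was 18 without JAX 1, 16 without JAX 4, 16 without TAC 2 and 23 without TAC 3. Of the 22 named genes that passed, 11 passed with any 1 library left out (Wdfy1, Mid1, Serpine2, Camk2b, Lepr, Pck2, Tmem98, Dnajc3, Pdia4, Nnt and Entpd4). Saa1 and Obp2a, for example, reached adjusted p of up to 0.151 and 0.219, and Hspa5 up to 0.0910 (without JAX 3, JAX 4 or TAC 2). Vendor, microbiota, housing and substrain were not separable in this comparison.

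The second comparison varied the donor, GF_TAC against GF_JAX. Depth and library type also differed, and cage and donor animal are not labelled. Here 4 of 20 ER stress genes fell with the TAC donor and 16 did not pass, with 13 falling adjusted over the list alone (camera adjusted p = 7.05e-12, and adjusted p = 0.0848 with an estimated correlation). Hspa5 was 1.61-fold lower (244 ± 19.5 against 396 ± 51.6 RPKM, n = 5 and 5, adjusted p = 0.00193). Hyou1, a chaperone of the same compartment, was 1.97-fold lower (52.6 ± 3.70 against 106 ± 18.04 RPKM, adjusted p = 0.0114) and Pdia4 1.47-fold lower (123 ± 6.08 against 182 ± 21.4 RPKM, adjusted p = 0.0103). The cytosolic chaperone Hsph1 was 2.33-fold lower (20.9 ± 3.52 against 50.7 ± 12.5 RPKM, adjusted p = 0.00319). Soat2, which esterifies cholesterol, was 1.39-fold higher (57.9 ± 5.41 against 41.4 ± 1.58 RPKM, adjusted p = 0.0415).

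The other named genes that fell were Chordc1, a partner of Hsp90 (-0.76, adjusted p = 0.0459), and the cytosolic chaperone Hspa8 (-0.59, adjusted p = 0.0464). Hsp90b1, the Hsp90 of the ER, fell too (-0.54, 219 ± 14.6 against 320 ± 40.9 RPKM, adjusted p = 0.0248), as did Lman1, a cargo receptor for secreted proteins (-0.52, adjusted p = 0.0277). Besides Soat2, Neurl2 (0.89, adjusted p = 0.0496) and Ing2 (0.48, adjusted p = 0.0464) rose. The cytokine gene Cntf averaged 1.005 ± 0.347 RPKM in GF_TAC and was listed at 0 in all 5 GF_JAX libraries (adjusted p = 0.0459). These rest on few reads, and Cntf shares its locus. The substrain markers Nnt (-0.13, adjusted p = 0.652), Wdfy1 (-0.18, adjusted p = 0.733) and Entpd4 (-0.20, adjusted p = 0.420) and the bile acid enzymes Cyp7a1 (-0.01, adjusted p = 0.995) and Cyp8b1 (-0.11, adjusted p = 0.722) did not pass.

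None of the 17 male-biased genes passed over all genes and 13 fell adjusted over the list alone (adjusted p = 3.13e-10, and adjusted p = 0.0972 with an estimated correlation), with Selenbp2 at -0.72 (adjusted p = 0.136) and Cyp7b1 at -0.62 (adjusted p = 0.180). The 8 female-biased genes tested all lay higher, 1 of them past the threshold adjusted over the list alone (adjusted p = 0.00221, and adjusted p = 0.323 with an estimated correlation), with Cyp3a44 at 1.01 (adjusted p = 0.0808). The female-biased call was lost without GF_JAX 3 (adjusted p = 0.0650). All 13 gluconeogenesis genes lay lower, 8 of them past the threshold adjusted over the list alone (adjusted p = 2.34e-08, and adjusted p = 0.144 with an estimated correlation). Among them were Tat (-0.62, adjusted p over all genes 0.0607), the glucose-6-phosphatase G6pc (-0.63, 0.0650) and Pck1 (-0.49, 0.180). In the amino acid list 2 of 21 fell adjusted over the list alone (adjusted p = 2.94e-09, and adjusted p = 0.334 with an estimated correlation), with Kmo at -0.31 (adjusted p = 0.102). In bile acid synthesis 3 of 13 fell adjusted over the list alone (adjusted p = 5.45e-06, and adjusted p = 0.323 with an estimated correlation).

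Immediate early and heat shock genes, a sign of handling, went with this comparison. Of 17, 2 fell (Hsph1 and Hspa8), and Hsp90aa1 stood at -0.67 (adjusted p = 0.0808). Adjusted over the list alone 5 fell and 1 rose (adjusted p = 0.0215, and adjusted p = 0.344 with an estimated correlation). This call was lost without GF_JAX 5 (adjusted p = 0.292) and without GF_TAC 5 (adjusted p = 0.0714). Respiratory chain genes were lower in 30 of 30 members (median -0.17, adjusted p = 5.45e-06, and adjusted p = 0.527 with an estimated correlation) and ribosomal protein genes in 29 of 30 (median -0.18, adjusted p = 2.89e-05, and adjusted p = 0.568 with an estimated correlation). With depth as a term both turned upward (adjusted p = 0.000715 and 1.10e-06), as did the acute phase list (adjusted p = 0.969). Lower lists with no member passing were fatty acid oxidation and PPARa targets (adjusted p = 2.55e-06), acute phase (0.000965), sinusoidal endothelial cells (0.00230) and fatty acid synthesis (0.0259). With an estimated correlation the first 3 had adjusted p = 0.453 and the last adjusted p = 0.527. The fatty acid synthesis call was lost without GF_JAX 1, GF_JAX 3 or GF_JAX 4 (adjusted p = 0.302, 0.329 and 0.0581) and without both GF_JAX 1 and GF_JAX 4 (0.991), which also ended the PPARa call (0.0569). The acute phase call was lost without GF_JAX 5 (0.0872), and the endothelial call without GF_JAX 5 (0.0835) or GF_TAC 2 (0.0683). The 5 B and plasma cell genes tested lay higher with none passing (median 0.57, adjusted p = 0.0366, and adjusted p = 0.453 with an estimated correlation). That call was lost without GF_JAX 1 and GF_JAX 4 together (0.212) and without GF_JAX 1, 3, 4 or 5 (0.0598, 0.0520, 0.0581 and 0.220) or GF_TAC 2 or 5 (0.293 and 0.170). Depth as a term also ended the calls of amino acid breakdown (0.608), bile acid synthesis (0.323), PPARa targets (0.232), fatty acid synthesis (0.345), B and plasma cells (0.608) and immediate early genes (0.0684). Quality weights ended those of fatty acid synthesis (0.707) and B cells (0.418; 0.128 with TPM), and the shared-start correction those of fatty acid synthesis (0.0587), the acute phase (0.0559), the ribosomal (0.249) and the respiratory list (0.105). The other 16 lists did not pass (adjusted p from 0.0635 to 0.966).

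In all, 21 genes passed between GF_TAC and GF_JAX, 7 higher and 14 lower, 19 of them without overlap of the libraries (1.81% of all genes tested, 0.794% by chance). The count was 24 without GF_JAX 1 and GF_JAX 4 (7 among the 21) and 11 with no filter. It was 28 with library type (9 among the 21) and 21 with depth as a term (11). The higher and lower calls were 23 and 8 with TPM, 3 and 13 after quantile normalisation, and 4 and 16 with the shared-start correction. It ranged from 5 to 111 with 1 library left out (9 without GF_JAX 1, 65 without GF_JAX 2, 12 without GF_JAX 3, 111 without GF_JAX 5, and 8, 7, 5, 12 and 8 without GF_TAC 1 to 5 in turn). A limma fit of these 10 libraries alone called 0 genes (1207 at an unadjusted p under 0.05, lowest adjusted p 0.0562). Of the 12 named genes that passed, Hsph1, Hyou1, Hspa5 and Pdia4 passed with any 1 library left out, and the others lost the call in 5 to 8 of 10 fits (Soat2 in 7, adjusted p up to 0.118).

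**Figure D2:**
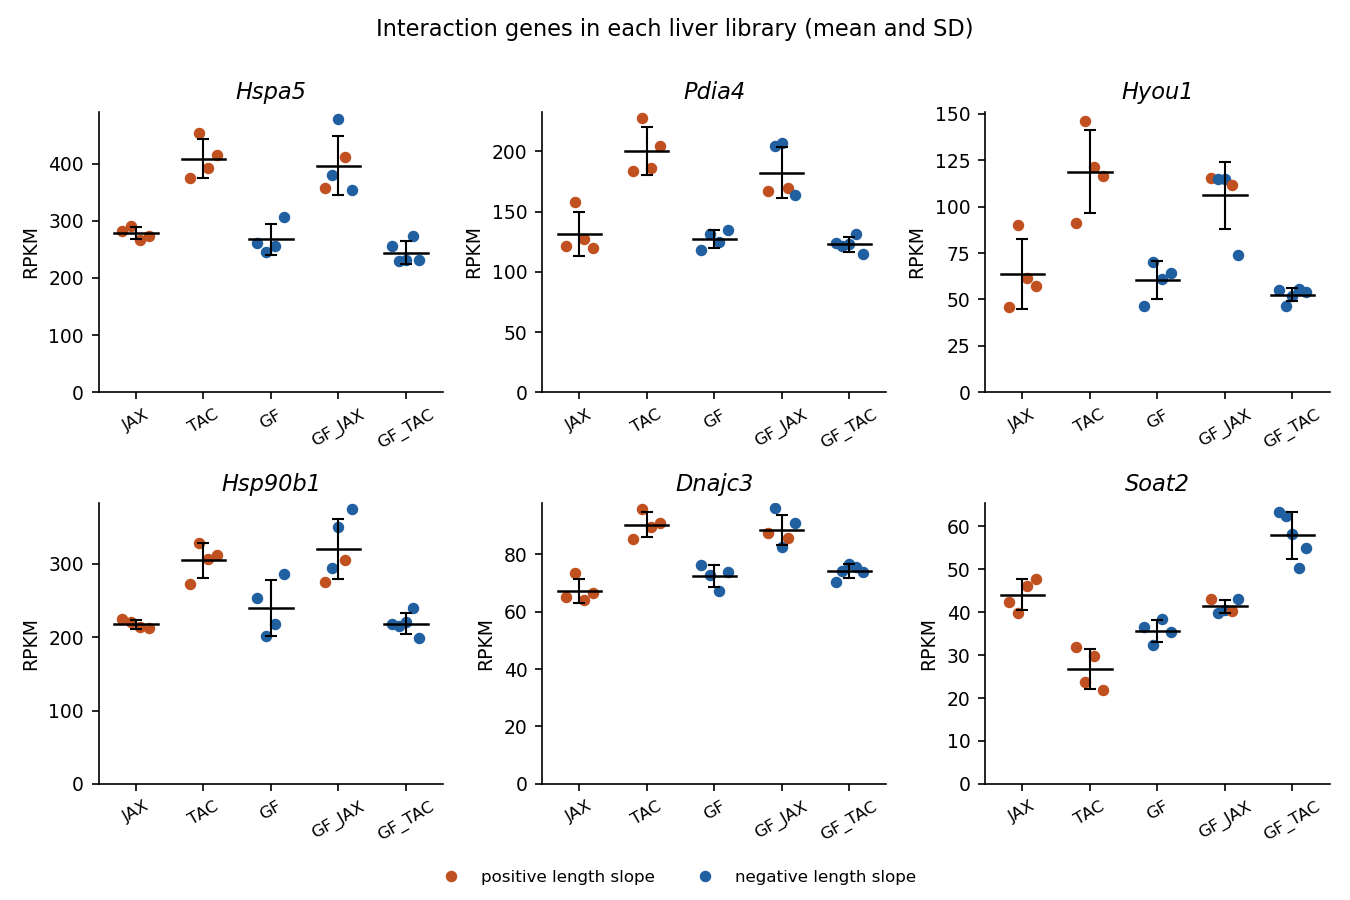
RPKM of Hspa5, Pdia4, Hyou1, Hsp90b1, Dnajc3 and Soat2 in each of the 22 livers by group, with the mean (bar) and SD (whiskers); orange points are libraries with a positive and blue points libraries with a negative transcript-length slope. Hspa5 averages 409 RPKM in TAC and 278 in JAX, but 244 in GF_TAC and 396 in GF_JAX.

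The 2 donor differences were then compared directly. Tested gene by gene, the donor difference in recipients departed most from that in vendor mice for Hspa5 (-1.24 ± 0.135, SE, adjusted p = 0.000101), Pdia4 (-1.17 ± 0.134, adjusted p = 0.000111), Soat2 (1.18 ± 0.138, adjusted p = 0.000111), Hyou1 (-1.89 ± 0.240, adjusted p = 0.000331), Dnajc3 (-0.67 ± 0.0893, adjusted p = 0.000555) and Hsp90b1 (-1.02 ± 0.144, adjusted p = 0.00114). Hspa5, Pdia4 and Hyou1 passed in both comparisons, higher in TAC than in JAX and lower in GF_TAC than in GF_JAX. Soat2 passed in both the other way (-0.71, adjusted p = 0.00148, between the vendors). Dnajc3 did not pass between recipients (-0.25, adjusted p = 0.0945), and Hsp90b1 did not pass between vendors (0.48, adjusted p = 0.0643). In all 182 genes passed this interaction test, 59 upward and 123 downward, and the 6 named genes passed with any 1 library left out. Of the 20 ER stress genes 11 fell in this test and 14 did so adjusted over the list alone (median -0.93, adjusted p = 3.94e-18, and adjusted p = 0.0142 with an estimated correlation), which held by both tests.

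Genes of amino acid breakdown (2 of 21 fell, 18 adjusted over the list alone; adjusted p = 2.01e-12), the acute phase (2 of 27, 17 alone; 5.97e-12), male-biased genes (3 of 17, 12 alone; 1.17e-11), gluconeogenesis (2 of 13, 9 alone; 1.89e-07) and bile acid synthesis (1 of 13, 8 alone; 1.51e-06) had a lower donor difference in recipients as well. With an estimated correlation these lists had adjusted p = 0.206, 0.157, 0.0673, 0.157 and 0.219. PPARa targets (0 of 31 by limma; adjusted p = 0.00593, and adjusted p = 0.714 with an estimated correlation) and Kupffer cells (0 of 18 by limma; adjusted p = 0.0236, and adjusted p = 0.714 with an estimated correlation) followed. The PPARa call was lost without GF_JAX 1 and GF_JAX 4 (adjusted p = 0.319). The Kupffer call was lost without any of JAX 1, JAX 3, TAC 3, GF_JAX 3, GF_JAX 5, GF_TAC 2 and GF_TAC 5 (adjusted p = 0.174, 0.0962, 0.156, 0.0665, 0.0729, 0.108 and 0.0940). The female-biased list (1 of 8 rose, 2 alone; adjusted p = 0.00450, and adjusted p = 0.271 with an estimated correlation) and the interferon list (1 of 30 rose, 1 alone; adjusted p = 0.00941, and adjusted p = 0.689 with an estimated correlation) had a higher one. The interferon call was lost without JAX 2 (adjusted p = 0.0774). The respiratory chain (30 of 30 members negative, adjusted p = 3.07e-07) and ribosomal (29 of 30, adjusted p = 3.67e-06) lists moved with them. Both had adjusted p = 0.689 with an estimated correlation and turned upward with depth as a term (adjusted p = 0.000765 and 3.16e-07), as did PPARa targets (0.739), while bile acid synthesis (0.241) and Kupffer cells (0.0875) lost the call. The shared-start correction ended the PPARa (0.192), ribosomal (0.192) and respiratory calls (0.0719), and quality weights the Kupffer call (0.0594). The other 18 lists did not pass (adjusted p from 0.108 to 0.926).

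Across all 12264 genes the log2 differences TAC minus JAX and GF_TAC minus GF_JAX had Pearson r = -0.247 and Spearman rho = -0.361, and 36.8% of genes had the same sign in both. Genes are not independent replicates, so recipient libraries were permuted: r had p = 0.00794, the smallest that assignments of the 10 libraries to 5 and 5 allow (two-sided exact permutation test). With GF_JAX 1 and GF_JAX 4 left out, r was -0.223 and the exact permutation p was 0.0536, where 0.0179 was the smallest possible. Over the 36 genes that passed between the vendors r was -0.387, with exact permutation p = 0.302. The interaction count was 302 with TPM, 112 with quantile normalisation, 283 with quality weights, 102 with depth as a term and 205 without GF_JAX 1 and GF_JAX 4. With TPM the median difference of all genes was 0.18 in the interaction (0.0165 without), -0.18 in GF minus JAX (0.00985) and -0.0780 in GF minus TAC (0.0241), and the interaction calls turned to 231 upward and 71 downward. It ranged from 90 to 380 with 1 library left out: 119, 99 and 90 without JAX 1, 3 or 4, 92 and 114 without TAC 2 or 3, 380 and 314 without GF_JAX 2 or 5, and 104, 116, 120 and 116 without GF_TAC 1, 2, 3 or 5.

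**Figure D3:**
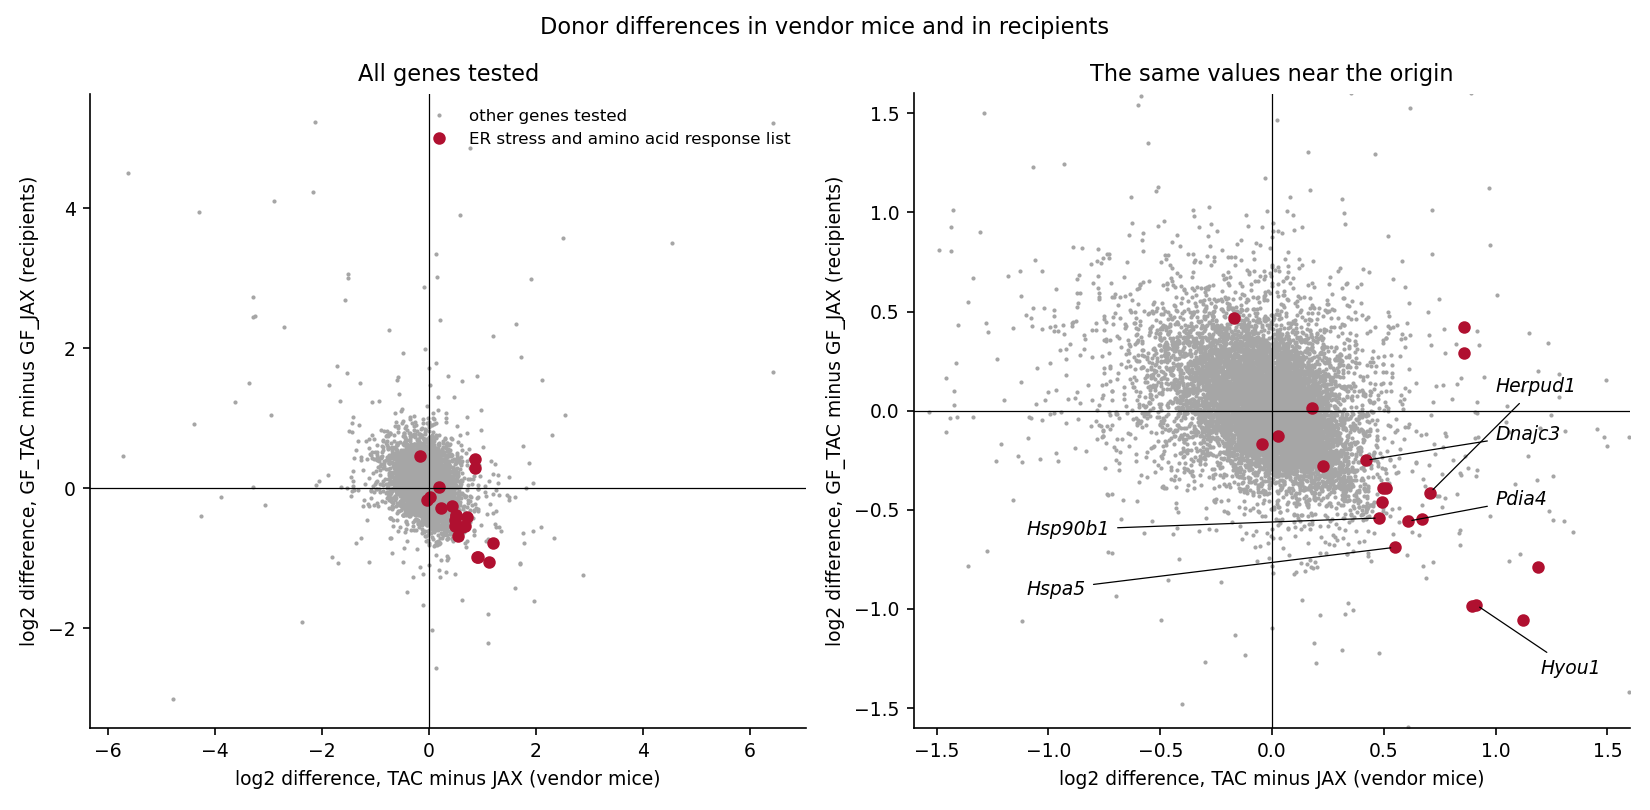
Log2 difference TAC minus JAX (x axis, vendor mice) against GF_TAC minus GF_JAX (y axis, recipients) for 12264 genes (grey; r = -0.247) and for the 20 members of the ER stress and amino acid response list (red); the right panel enlarges the area around the origin. Hspa5 lies at 0.55 and -0.69 and Hyou1 at 0.91 and -0.98.

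The next comparisons asked what colonisation changed relative to germ-free mice. With JAX contents, the deiodinase Dio1, which activates thyroid hormone, rose 1.96-fold (222 ± 42.6 in GF_JAX against 112 ± 16.6 RPKM in GF, n = 5 and 4, adjusted p = 0.00164). Csad, an enzyme of taurine synthesis, rose 1.85-fold (240 ± 61.8 against 126 ± 12.8 RPKM, adjusted p = 0.0106). The estrogen sulfotransferase Sult1e1 fell 5.42-fold (1.19 ± 1.16 against 10.3 ± 4.02 RPKM, adjusted p = 0.0247). Hspa5 rose 1.47-fold (396 ± 51.6 against 268 ± 27.2 RPKM, adjusted p = 0.0106), and Pdia4 rose 1.42-fold (182 ± 21.4 against 127 ± 7.25 RPKM, adjusted p = 0.0175).

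The other large increases in GF_JAX were the kinase Aatk (1.27), the carboxylesterase Ces2c (1.13), Mogat1, an enzyme of triglyceride synthesis (1.05), Fam102a (1.01), the cytochrome P450 Cyp3a59 (0.91) and the NF-kB subunit Rel (0.89). Their adjusted p ran from 0.0160 (Fam102a) to 0.0471 (Rel). The decreases were Gpx6 (-1.81), the centromere gene Cenpm (-1.42), Fxyd7 (-1.32), the proton pump subunit Atp6v0d2 (-1.29), C1qtnf7 (-1.25) and the noncoding RNAs Dio3os (-1.22) and Snhg5 (-1.21). Their adjusted p ran from 0.0106 (Snhg5) to 0.0470 (C1qtnf7). Of the ER stress list 4 of 20 rose, with Hyou1 at 0.80 (adjusted p = 0.0403) and Dnajc3 at 0.28 (adjusted p = 0.0470). Adjusted over the list alone 9 rose and 1 fell (camera adjusted p = 8.83e-07, and adjusted p = 0.519 with an estimated correlation).

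Core clock genes rose only adjusted over the list alone (5 of 17), with Bhlhe40 at 1.09 (adjusted p = 0.0605) and Dbp at 1.40 (adjusted p = 0.112). The set test gave adjusted p = 0.0119, and adjusted p = 0.621 with an estimated correlation. NRF2 targets (3 of 14 rose adjusted over the list alone, Gclc at 0.65 with adjusted p = 0.0944; set test 0.0144), bile acid synthesis (3 of 13 alone; 0.00698) and male-biased genes (0 of 17 by limma; 0.00101) were also higher, each with adjusted p = 0.621 with an estimated correlation. So were fatty acid synthesis (0.0144, and adjusted p = 0.699 with an estimated correlation), PPARa targets (0.0187, and adjusted p = 0.910 with an estimated correlation) and bile acid transport and FXR targets (0.0473, and adjusted p = 0.621 with an estimated correlation), with no member passing. GF_JAX 1 and GF_JAX 4 had the length slope of the vendor libraries. Without them bile acid synthesis (0.0267) and male-biased genes (0.000566) passed, but the adjusted p was 0.238 for the clock, 0.0805 for NRF2 targets, 0.617 for fatty acid synthesis and 0.717 for PPARa targets, and bile acid transport turned downward (0.950). Single libraries ended calls too. Bile acid synthesis was at 0.0888 without GF 2, NRF2 targets at 0.0573 without GF 2 and 0.118 without GF_JAX 3, and fatty acid synthesis at 0.0941 without GF_JAX 1 and 0.226 without GF_JAX 3. PPARa targets were at 0.1002, 0.716, 0.0871, 0.128 and 0.156 without GF 1, GF 2, GF_JAX 1, GF_JAX 4 or GF_JAX 5, and bile acid transport at 0.0575, 0.122, 0.0870, 0.0941 and 0.298 without GF 1, GF 2, GF 3, GF_JAX 1 or GF_JAX 4. Depth as a term and quality weights ended the calls of bile acid synthesis (0.336 and 0.0977), bile acid transport (0.202 and 0.295), fatty acid synthesis (0.0834 and 0.270) and PPARa targets (0.486 and 0.381), and the weights that of NRF2 targets (0.164). The shared-start correction ended those of bile acid transport and PPARa targets (both 0.0536). The other 22 lists did not pass (adjusted p from 0.0556 to 0.974). In the female-biased list Atp6v0d2 fell; without GF_JAX 1 and GF_JAX 4 this list and cholesterol synthesis passed downward (0.00981 and 0.00128). The acute phase list had a median of 0.11, a mean of -0.10 and a set test that pointed up (adjusted p = 0.779). Cyp7a1 stood at 0.66 (21.9 ± 11.7 against 13.6 ± 7.17 RPKM, adjusted p = 0.412) and Cyp8b1 at 0.07 (adjusted p = 0.831).

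In all, 75 genes passed between GF_JAX and GF, 42 higher and 33 lower, 55 without overlap of the libraries (2.70% of all genes tested, 1.59% by chance). The count was 29 without GF_JAX 1 and GF_JAX 4, 45 with library type as a term and 28 with TPM. A limma fit of these 9 libraries alone called 0 (977 at an unadjusted p under 0.05, lowest adjusted p 0.160). It ranged from 6 to 251 with 1 library left out: 6, 200, 7 and 18 without GF 1, 2, 3 and 4, and 22, 186, 42 and 251 without GF_JAX 1, 2, 4 and 5. Of the 20 named genes that passed, Dio1 passed with any 1 library left out. Csad and Snhg5 were lost only without GF 3 (both adjusted p = 0.0519), Fam102a, Gpx6, Fxyd7, Hspa5 and Pdia4 only without GF 1 or GF 3, and the others without 4 to 6 of the libraries.

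With TAC contents, Cyp3a59 rose 2.40-fold (54.2 ± 9.98 in GF_TAC against 22.5 ± 6.90 RPKM in GF, n = 5 and 4, adjusted p = 0.00272) and Csad 2.09-fold (265 ± 31.7 against 126 ± 12.8 RPKM, adjusted p = 0.00272). Slc40a1, the iron exporter ferroportin, rose 1.87-fold (57.4 ± 6.23 against 30.7 ± 6.67 RPKM, adjusted p = 0.0330). Sult1e1 fell 5.12-fold (1.56 ± 1.91 against 10.3 ± 4.02 RPKM, adjusted p = 0.0385), and Got1, a transaminase of the gluconeogenesis list, fell 1.62-fold (173 ± 24.1 against 280 ± 33.8 RPKM, adjusted p = 0.0330).

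Cyp3a44 (1.25), Wfdc2 (1.203), Mab21l2 (1.12), Pcgf2 (1.08) and the kinase Dapk2 (0.96) rose as well, with adjusted p from 0.0196 (Mab21l2) to 0.0330, while Fxyd7 (-1.31, adjusted p = 0.0173) and the phosphatase Lhpp (-0.64, adjusted p = 0.0150) fell. Cyp3a44 and Mab21l2 were close to the floor, at 1.93 ± 1.26 and 2.17 ± 0.825 RPKM in GF_TAC. Gluconeogenesis genes lay lower in 13 of 13 members, of which Got1 fell over all genes and 2 fell adjusted over the list alone, with Igfbp1 at -0.82 (adjusted p = 0.147). The set test gave adjusted p = 7.69e-06, and adjusted p = 0.299 with an estimated correlation. All 21 amino acid genes lay lower with none passing (adjusted p = 1.28e-05, and adjusted p = 0.591 with an estimated correlation). Stellate cell and fibroblast genes lay higher in 14 of 14 members with none passing (adjusted p = 0.000399, and adjusted p = 0.299 with an estimated correlation), among them Col1a1 (0.67, adjusted p = 0.493) and Pdgfrb (0.46, adjusted p = 0.312). B and plasma cell genes lay higher in 5 of 5, of which 2 rose adjusted over the list alone (adjusted p = 0.000628, and adjusted p = 0.2998 with an estimated correlation), with Cd79b at 1.22 (adjusted p = 0.319) and Cd79a at 1.06 (adjusted p = 0.451). NRF2 targets were higher with none passing (adjusted p = 0.00246, and adjusted p = 0.396 with an estimated correlation; Gstm4 0.45, adjusted p = 0.348).

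Lower lists with no member passing over all genes were the acute phase (adjusted p = 0.00202, and adjusted p = 0.633 with an estimated correlation), male-biased genes (0.0239, and adjusted p = 0.633 with an estimated correlation) and immediate early and heat shock genes (1 of 17 alone; 0.00202, and adjusted p = 0.299 with an estimated correlation). Ribosomal (30 of 30 members lower; 1.28e-05, and adjusted p = 0.6502 with an estimated correlation) and respiratory chain genes (30 of 30; 0.000295, and adjusted p = 0.704 with an estimated correlation) lay lower with them. GF 4, the shallowest GF library, carried several of these. Without it the ribosomal list was at 0.101, the respiratory at 0.302, the acute phase at 0.0778 and the male-biased at 0.0645. The male-biased call was lost without GF 2, GF_TAC 2 or GF_TAC 5 as well (0.127, 0.0775 and 0.108), and that of immediate early genes without GF 3 (0.0762). Depth as a term ended the male-biased (0.287), acute phase (0.0585) and respiratory calls (0.0680), and quality weights (0.315) and the shared-start correction (0.0511) the male-biased one. Among the other 20 lists (adjusted p from 0.110 to 0.707), Cyp3a59 and Cyp3a44 rose in the CAR and PXR list, the latter also in the female-biased list, and Slc40a1 in the Kupffer list. Cyp7a1 stood at 0.65 (20.7 ± 7.63 against 13.6 ± 7.17 RPKM, adjusted p = 0.703).

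In all, 25 genes passed between GF_TAC and GF, 21 higher and 4 lower, and in all 25 the libraries did not overlap (3.79% of all genes tested, 1.59% by chance). The count was 31 without GF_JAX 1 and GF_JAX 4 in the shared fit and 79 with quality weights. It was 10, 13, 14 and 6 without GF 1, 2, 3 and 4, and 8, 16, 16 and 16 without GF_TAC 1, 2, 4 and 5. Of the 12 named genes that passed, Cyp3a59 and Csad passed with any 1 library left out, and the others lost the call in 3 to 8 of 9 fits (Slc40a1 in 7, Sult1e1 in 6, Got1 in 8).

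Both colonisations shared 8 called genes: Ces2e, Csad, Cyp3a59, Dio1 and Notum rose in both, and Fxyd7, Lhpp and Sult1e1 fell in both; Ces2e and Notum were named after their values were seen. Independent lists of these sizes would share 0.0719 and 0.0108 genes. Simulated unchanged groups shared 0 but had at most 1 call per direction, so this is no yardstick. Both comparisons used the same GF livers: r of their log2 differences was 0.643, within the range of 100 simulations (mean 0.547, highest 0.651). The covariance was 0.0807 against a simulated mean of 0.0419 (highest 0.0572), a difference of 0.0388. With the GF libraries split 2 and 2 between the comparisons, 0 calls were shared by limma in each of 6 splits, at which up to 39 and 8 genes rose in the single comparisons. There r was 0.156 to 0.350, with covariances of 0.0277 to 0.0535. The shared count was 5 without GF_JAX 1 and GF_JAX 4, 4, 4 and 2 without GF 1, GF 3 or GF 4, 15 without GF_JAX 5 and 4 without GF_TAC 1. The substrain markers Nnt, Wdfy1 and Entpd4 did not pass in either comparison (adjusted p from 0.183 to 0.948).

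The last comparisons set germ-free mice against each vendor. Cyp2b10, a cytochrome P450 induced through the receptor CAR, averaged 234 ± 82.8 RPKM in GF, 11.7 ± 4.90 in JAX and 13.5 ± 9.07 in TAC (n = 4 each; log2 difference 4.23 and 4.33, adjusted p = 0.000108 and 0.000278). Cyp2c55, another drug-metabolising enzyme, averaged 20.7 ± 8.65 against 1.90 ± 0.928 and 1.95 ± 0.219 RPKM (2.86 and 2.79, adjusted p = 6.05e-05 and 0.000278). Cyp7a1 averaged 13.6 ± 7.17 RPKM in GF against 54.5 ± 25.3 in JAX and 40.2 ± 16.6 in TAC (-1.95 and -1.57, adjusted p = 0.00310 and 0.0113). Apolipoprotein A-IV (Apoa4) fell 4.16-fold relative to TAC (129 ± 19.7 against 538 ± 72.5 RPKM, adjusted p = 8.44e-07). The lipid droplet protein Cidec fell 21.3-fold relative to JAX (4.25 ± 1.61 against 106 ± 4.41 RPKM, adjusted p = 7.64e-06). All GF libraries had a negative and all vendor libraries a positive transcript-length slope. With library type as a term 237 genes passed against JAX (140 of the 2939 passing without it) and 72 against TAC (42 of 2977).

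Against JAX, large increases besides Cyp2b10 and Cyp2c55 were those of Rsc1a1 (4.39), the acute phase protein Orm3 (4.25), the male-biased steroid enzyme Hsd3b5 (3.56; 138 ± 39.0 against 12.0 ± 8.38 RPKM), Sult1e1 (3.19) and Gpx6 (2.79). Large decreases were those of Tgoln2, a protein of the trans-Golgi (-4.92), Cidec (-4.41), the sulfotransferase Gal3st1 (-3.04), the lipase Abhd2 (-3.00), Cntnap1 (-2.99) and Cgref1 (-2.91). The adjusted p of these genes ran from 2.51e-06 (Cntnap1) to 0.00476 (Rsc1a1). Once library type was a term, Cyp2b10 (5.13, adjusted p = 0.00837), Cyp2c55 (3.59), Hsd3b5 (2.83, adjusted p = 0.0248), Gpx6 (3.25), Cidec (-3.51, adjusted p = 0.0194), Gal3st1 (-2.85), Cntnap1 (-2.78) and Cgref1 (-2.96) passed. Orm3 (2.57, adjusted p = 0.134) and Sult1e1 (2.97, adjusted p = 0.0751) did not, Tgoln2 (-0.02) and Abhd2 (-0.33) came close to 0, and Rsc1a1, which lies within the locus of another gene, reversed to -0.64. Tgoln2 stood at 38.9 and 51.9 RPKM in GF_JAX 1 and GF_JAX 4 and at no more than 2.62 in the other GF_JAX libraries. For Cyp7a1 the difference was -2.21 with the term, with a wider SE (0.684 against 0.412) and adjusted p = 0.105. Nnt was higher in GF than in JAX (0.41, adjusted p = 0.0324; 1.05 with the term), a call lost with any 1 library left out (adjusted p from 0.0510 to 0.0738). Wdfy1 (0.17, adjusted p = 0.623), Entpd4 (-0.31, adjusted p = 0.0675) and Cyp8b1 (-0.21, adjusted p = 0.297) did not pass.

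Against JAX, 18 of 24 cholesterol synthesis genes rose and none fell (18 adjusted over the list alone; adjusted p = 1.89e-07), with Mvd at 2.46, Fdps at 1.73 and Mvk at 1.67. Of the CAR and PXR targets 14 of 27 rose (15 alone; 5.36e-07), with Cyp2c29 at 1.44 (590 ± 144 against 214 ± 22.04 RPKM) and Cyp2c54 at 1.34. In the acute phase list 9 of 27 rose (11 alone; 2.62e-05), with Saa1 at 2.36 and Saa4 at 1.22. In the Kupffer list 12 of 18 rose and 1 fell (13 and 1 alone; 0.000113), with Lyz2 at 0.88. Of the PPARa targets 11 of 31 fell and 1 rose (14 and 1 alone; 0.000168), with Acot2 at -1.84, Pdk4 at -1.55 and Ehhadh at -1.01. Male-biased genes (5 of 17 rose, 5 alone; 0.00633), sinusoidal endothelial genes (7 of 15 rose, 7 alone; 0.00633; Stab2 0.63), antigen presentation (4 of 13 rose, 7 alone; 0.00633; Cd74 0.73) passed as well. So did amino acid breakdown (7 of 21 rose and 1 fell, 9 and 1 alone; 0.0134, 0.1202 without JAX 2, 0.113 without GF 4, 0.219 with depth as a term and 0.0706 in the fit of only these groups). Depth as a term ended the male-biased call (0.0653). The ribosomal (14 of 30 rose, 28 alone; 5.36e-07) and respiratory chain lists (7 of 30 rose, 23 alone; 2.97e-06) moved with them. The amino acid list had adjusted p = 0.732 with an estimated correlation, and each of the others adjusted p = 0.649 with an estimated correlation. After library type was added as a term the cholesterol (3.77e-15), CAR and PXR (2.79e-09), acute phase (2.07e-05), Kupffer (0.00119), male-biased and antigen presentation (both 0.0141) and amino acid lists (0.00216) passed and the PPARa (0.464), endothelial (0.0609), ribosomal (0.0887) and respiratory lists (0.368) did not. Of the members named here only Cyp2c29 and Cyp2c54 passed singly with the term (0.00387 and 0.00493; the others from 0.0773 to 0.497). The other 19 lists did not pass (adjusted p from 0.0834 to 0.9799), although single members did. Among them were Cyp1a2 in the AHR list (1.06) and Nr0b2, the FXR target SHP (1.47). The pancreatic protease Cela1 (51.3 ± 9.58 against 16.9 ± 3.06 RPKM, adjusted p = 0.000848), 1 of 2 tested members of the pancreas list, rose as well and was named after its value was seen.

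Against TAC, Insl3 (3.31), Sult1e1 (2.61), the mucin-associated peptide Tff3 (2.44) and Gstm3 (2.03) rose. Rsc1a1, at 38.3 ± 16.6 RPKM in GF, was listed at 0 in all 4 TAC libraries. Tgoln2 (-5.05), Cidec (-3.18), Abhd2 (-2.84), Apoa4 (-2.06) and Acss3 (-2.04) fell. With library type as a term Cyp2b10 (adjusted p = 0.0214), Cyp2c55 (0.0152), Apoa4 (0.00618), Cyp2c54 (0.0318; 1.12 without the term) and Pdia4 (0.0216; -0.65 without the term) passed. Cidec (-2.27, adjusted p = 0.191), Insl3 (3.53, 0.0535), Sult1e1 (2.39, 0.208), Gstm3 (1.81, 0.134) and Cyp7a1 (-1.83, 0.242) lost the call, as did Tff3 (0.999), Tgoln2 (-0.15), Abhd2 (-0.17) and Rsc1a1 (0.12). Acss3 went to -0.03, and Nnt, lower in GF than in TAC (-0.52, adjusted p = 0.0105), reversed to 0.13. Wdfy1 (-1.33) fell and Entpd4 (0.53) rose, with adjusted p = 0.00110 and 0.00574 (0.246 and 0.174 with the term).

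Of 24 cholesterol synthesis genes 11 rose (16 alone; adjusted p = 0.000221), with Mvk at 1.64 and Pmvk at 1.12. Of 31 PPARa targets 12 fell and 1 rose (13 and 1 alone; 0.000221), with Ehhadh at -0.95 and Hadha at -0.53. Of 27 CAR and PXR targets 10 rose (10 alone; 0.000353). Of 20 ER stress genes 7 fell and 1 rose (8 and 1 alone; 0.00162), with Hyou1 at -0.96 and Hspa5 at -0.61. Sinusoidal endothelial genes (5 of 15 rose, 6 alone; 0.00725; Stab2 0.80), antigen presentation (4 of 13, 4 alone; 0.00725; H2-Eb1 0.80 and Cd74 0.71) and Kupffer genes (4 of 18 rose and 1 fell, 7 and 1 alone; 0.00736, 0.0621 without TAC 2; Timd4 1.13) were higher. Core clock genes were lower (2 of 17 fell and 1 rose, 2 and 1 alone; 0.0125; Cry1 -0.98). Ribosomal (0 of 30 by limma; 0.00162, 0.0718 without GF 4) and respiratory genes (1 of 30 rose; 0.0111, 0.0562 without GF 1 and 0.267 without GF 4) lay higher with them. All 10 lists had adjusted p = 0.925 with an estimated correlation. With library type as a term the PPARa (0.497), endothelial (0.0514), clock (0.904) and ribosomal lists (0.999) lost the call and the respiratory list turned downward (0.381). The members named here did not pass singly with the term (0.0504 to 0.857). The other 20 lists did not pass (adjusted p from 0.0796 to 0.992). Single members among them that rose were Cyp1a2 (0.79), Hsd3b5 (2.31), Cela1 (1.18) and Eno3 (0.78, adjusted p = 0.0413), 1 of 2 tested members of the skeletal muscle list. Cela1 and Eno3 were named after their values were seen. Fabp2, the only gut epithelium gene tested, stood at 0.27 (adjusted p = 0.189) and, against JAX, at -0.03 (adjusted p = 0.887).

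In all, 1430 genes were higher and 1509 lower in GF than in JAX, and 1362 higher and 1615 lower in GF than in TAC. Of these 794 were higher and 1089 lower in both, against 159 and 199 for independent lists; both comparisons use the same GF libraries and the same contrast of library types. When library type was a term 26 and 29 were shared, against 0.217 and 0.505 for independent lists. Libraries did not overlap for 27.9% and 25.8% of all genes tested (2.86% by chance). With TPM the calls were 565 higher and 2538 lower against JAX and 807 and 1670 against TAC, and with the shared-start correction 1832 and 1276 against JAX. The counts were 4003 and 4057 without GF_JAX 1 and GF_JAX 4, 5065 and 4824 with quality weights and, against JAX, 1541 with depth as a term. Against JAX they were 1752, 1573, 1546 and 1725 without JAX 2, JAX 4, GF 1 and GF 4, and against TAC 1952, 1866, 1677 and 1965 without TAC 3, TAC 4, GF 1 and GF 4. The named genes kept their calls with any 1 library left out in 29 of 30 (JAX, all but Nnt) and 31 of 31 cases (TAC).

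Among lists that did not pass, some had a median, a mean and a set test of different sign. Between the vendors these were NRF2 and PPARa targets, fatty acid synthesis, immediate early genes and the erythroid, adipose, endothelial and B cell lists. Between the recipients they were NRF2 targets, cell cycle, interferon, cholangiocytes and neutrophils, and in the interaction NRF2 targets, immediate early genes, antigen presentation, cholangiocytes, stellate cells and adipose tissue. Against GF they were the acute phase with JAX contents and bile acid transport, female-biased genes and neutrophils with TAC contents. Between GF and JAX they were AHR targets, immediate early genes and adipose tissue. Between GF and TAC they were both sex-biased lists, cell cycle, immediate early genes, neutrophils, cholangiocytes, erythroid cells and adipose tissue.

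**Figure D4:**
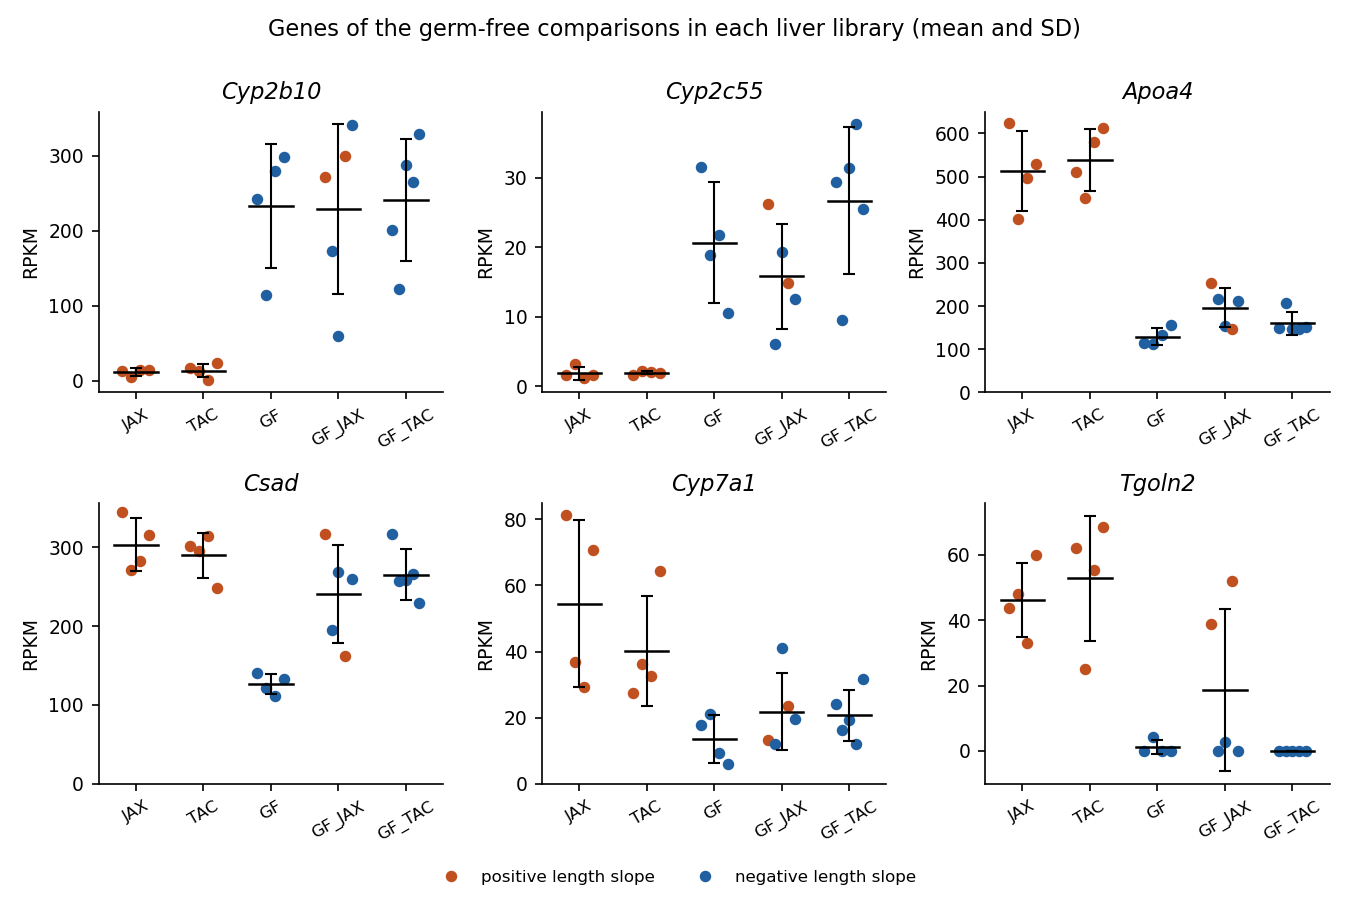
RPKM of Cyp2b10, Cyp2c55, Apoa4, Csad, Cyp7a1 and Tgoln2 in each of the 22 livers by group, with the mean (bar) and SD (whiskers); orange and blue points mark libraries with a positive and a negative transcript-length slope. Cyp2b10 averages 234, 229 and 241 RPKM in GF, GF_JAX and GF_TAC, and Tgoln2 follows the library type within GF_JAX.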

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

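Other splits of the libraries and the fit without GF_JAX 1 and GF_JAX 4 were chosen after the result was seen. The tests that removed trends and that kept genes of middle abundance were written before.

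The donor difference in recipients departed from that in vendor mice for 182 genes, tested as an interaction. The estimates had opposite signs in 178 of these, and 4 (Hspa5, Pdia4, Hyou1 and Soat2) passed in both comparisons. The 6 with the smallest p were Hspa5 (-1.24), Pdia4 (-1.17), Soat2 (1.18), Hyou1 (-1.89), Dnajc3 (-0.67) and Hsp90b1 (-1.02). Of 100 splits drawn only the real one gave as many genes (182 against at most 6 in the others), arguing against chance. Among lists, the adjusted p of the interaction was 3.94e-18 for ER stress, 2.01e-12 for amino acid breakdown, 5.97e-12 for the acute phase, 1.17e-11 for male-biased genes, 1.89e-07 for gluconeogenesis and 3.07e-07 for the respiratory chain. It was 1.51e-06 for bile acid synthesis, 3.67e-06 for ribosomal proteins, 0.00450 for female-biased genes, 0.00593 for PPARa targets, 0.00941 for interferon and 0.0236 for Kupffer cells. With an estimated correlation only the ER stress list passed (adjusted p = 0.0142).

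Trends of length, GC content and abundance between libraries were argued against as the whole cause of the negative correlation of both donor differences, since r across genes was -0.167 after they were removed (exact permutation p = 0.00794, the smallest possible; -0.276 before, p = 0.0159, 11169 genes). Over 6125 genes with a mean RPKM of 5 to 60, less prone to loss of reads, r was -0.197 (exact permutation p = 0.0238). Depth stays open, since these genes moved with it too (median slope 0.11 at 5 to 20 RPKM). TAC was shallower than JAX but GF_TAC deeper than GF_JAX. For the ER stress list the share owed to trends in length, GC and abundance cannot be told. Its median interaction went from -0.93 to -0.61 (quartiles -0.94 and -0.39), with 19 of 20 members negative, between the bounds set for either outcome. Library type stays open in part, since r was -0.223 (exact permutation p = 0.0536) without GF_JAX 1 and GF_JAX 4, with fewer libraries. An untested hypothesis is that the chaperone response to the donor may depend on the host, whose early life and possibly substrain and housing differed.

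Other values stood apart because 1 library lay far from the others of its group by a gap, as a share of the group's range, beyond Dixon's 95% critical value. Of 439 groups of values examined 34 did so (7.74%), where chance alone gives about 1 in 20. GF_JAX 4 had 3.93% of its RPKM in small nucleolar RNA genes against 0.136 to 1.08% in the other GF_JAX libraries (gap 0.750 of the range). For the mean log2 value of a list the gaps were 0.852 for cholesterol synthesis in JAX 1, 0.834 for AHR targets in GF 1, 0.955 for neutrophils in JAX 4, 0.802 for immediate early genes in GF_JAX 5, 0.944 for adipose tissue in TAC 3 and 0.806 for cholangiocytes in GF_TAC 5, all high. They were 0.851 for PPARa targets in TAC 2, 0.857 for gluconeogenesis in TAC 1, 0.889 for CAR and PXR targets in GF 2, 0.905 for female-biased genes in JAX 2, 0.772 for the core clock in GF_JAX 3, 0.723 for ER stress in GF_TAC 5, 0.780 for sinusoidal endothelium in GF_TAC 2 and 0.834 for cholangiocytes in TAC 1, all low.

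Single genes high in a library were Dbp in GF 1 (gap 0.944), Dclk3 in TAC 1 (0.865), Dio1 in GF_JAX 5 (0.766), Insl3 in TAC 1 (0.986), Saa4 in TAC 2 (0.847), Selenbp2 in GF_JAX 3 (0.752), Tgoln2 in GF 2 (0.997), Rsc1a1 in JAX 1 (0.998) and Wfdc2 in GF_TAC 2 (0.734). Fxyd7 was above 0 only in GF_JAX 2 and only in GF_TAC 1 within those groups, and Sult1e1 only in JAX 3 of the JAX libraries, which gives a gap of 1 in each. Low were Atp6v0d2 in GF_JAX 3 (0.872), Cyp2b10 in JAX 2 (0.894), Hyou1 in GF_JAX 5 (0.928), Lepr in JAX 1 (0.870) and in TAC 1 (0.924), Rsc1a1 in GF 2 (0.835) and Wdfy1 in TAC 2 (0.910). In GF 2, Tgoln2 stood at 4.29 RPKM against at most 0.00541 in the other GF libraries and Rsc1a1 at 14.1 against 41.2 to 50.8, both in the direction of the vendor libraries.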

How the results depend on the processing

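Library type or depth as a term, leaving out GF_JAX 1 and GF_JAX 4, and the shared-start correction were chosen after the results were seen. Median-ratio scaling, a pseudocount of 0.5, an RPKM minimum of 5 and the shared-start correction left every count of passing genes within 1.5 times its value. For the donor differences r was not computed with depth, library type, weights or block. Elsewhere it was negative with exact permutation p up to 0.0397, but for 2 settings with fewer genes or libraries. They were the 36 genes passing between the vendors (r = -0.387, p = 0.302) and leaving out GF_JAX 1 and GF_JAX 4 (-0.223, p = 0.0536). With library quality weights the counts were 218 for TAC minus JAX (36), 26 for GF_JAX minus GF (75), 79 for GF_TAC minus GF (25), 5065 for GF minus JAX (2939), 4824 for GF minus TAC (2977) and 283 for the interaction (182). With library type as a term they were 69, 45, 237 and 72 for TAC minus JAX, GF_JAX minus GF, GF minus JAX and GF minus TAC. Without GF_JAX 1 and GF_JAX 4 they were 62 for TAC minus JAX and 29 for GF_JAX minus GF, and 5 genes rather than 8 were shared by both colonisations. No filter gave 11 for GF_TAC minus GF_JAX (21) and 38 for GF_JAX minus GF, where the pseudocount of 0.1 gave 46 and TPM 28. TPM gave 302 and quantile normalisation 112 for the interaction, and depth as a term 102 there and 1541 for GF minus JAX. A limma fit of only the groups compared called 0 for GF_TAC minus GF_JAX (1207 at an unadjusted p under 0.05), 0 for GF_JAX minus GF (977) and 0 shared genes. With 1 library left out the counts ranged from 16 to 43 (TAC minus JAX), 5 to 111 (GF_TAC minus GF_JAX), 6 to 251 (GF_JAX minus GF), 6 to 21 (GF_TAC minus GF), 1546 to 3715 (GF minus JAX), 1677 to 3722 (GF minus TAC), 90 to 380 (interaction) and 2 to 15 (shared genes), and r from -0.269 to -0.197. Same-numbered libraries did not deviate together (r from -0.121 to 0.150 over 41 pairs, median 0.0126, and 2 of 22 libraries closest to their own number), so the numbers do not pair them. With the replicate block 7 genes passed for GF_TAC minus GF_JAX and 23 for GF_JAX minus GF, and all other counts stayed within 1.5 times. In the fit with library type Rsc1a1 (GF minus JAX, -0.64) and Nnt (GF minus TAC, 0.13) reversed, as did the lists for bile acid transport in GF_JAX minus GF (adjusted p = 0.963, and 0.950 without GF_JAX 1 and GF_JAX 4) and the respiratory chain in GF minus TAC (0.381). With depth as a term lists reversed in TAC minus JAX (CAR and PXR 0.907, ribosomal 0.000117, respiratory 0.0149), in GF_TAC minus GF_JAX (acute phase 0.969, ribosomal 1.10e-06, respiratory 0.000715) and in the interaction (PPARa 0.739, ribosomal 3.16e-07, respiratory 0.000765). Where no cause is given, the cause was not tested. Of 177 differences of named genes, 111 kept their side of the threshold with library type as a term, 61 lost their call and 3 gained one. Those kept were 129 in the fit of only the groups compared, 147 with TPM, 151 with no filter and 151 without GF_JAX 1 and GF_JAX 4, 154 with quality weights, 153 with the block, 156 with depth as a term, 161 with quantile normalisation, 165 with the pseudocount of 0.1, 165 of 175 with the shared-start correction, 174 with the pseudocount of 0.5, 176 with median-ratio scaling, and 154 of 155 at RPKM 5. Leaving out 1 library kept 1301 of 1577. Of 76 list calls, 2 held with an estimated correlation, 47 with depth as a term, 59 with library type as a term, 64 with the shared-start correction, 66 with quality weights and 67 without GF_JAX 1 and GF_JAX 4, all 76 with median-ratio scaling, 75 each with TPM, the block and the fit of only the groups compared, and 715 of 774 with 1 library left out. Depth of 1.35 to 3.79 M reads limits low genes, where 1 RPKM is a few reads, and the level of abundant genes, which fell with depth.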

Other observations

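All tests in this part (library type, kept and remaining shares, read ceiling, substrain markers and other splits) were chosen after the results were seen.

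In the fit with library type as a term, 55 genes passed against both vendors in the same direction, 26 with a positive and 29 with a negative fitted difference. The mean RPKM of GF lay on the fitted side of both vendor means in 44 of them, between these means in 3 and on the other side in 8, whose direction rests on the term (Abcc2, fitted higher, at 65.8 in GF against 74.5 in JAX and 87.7 in TAC). Besides the drug-metabolising cytochromes, the higher genes included the carboxylesterase Ces1g (157 RPKM in GF against 102 in JAX and 98.8 in TAC), the hydroxysteroid dehydrogenase Akr1c14 (123 against 87.4 and 111), the stress-regulated gene Ndrg1 (39.5 against 15.4 and 16.0) and the carbonic anhydrase-related gene Car8 (31.8 against 17.6 and 19.4), with adjusted p (limma) from 0.000856 to 0.0479. Among the lower genes were Wfdc2 (8.60 against 53.3 and 30.3), Raet1e, a ligand of the NK cell receptor NKG2D (3.77 against 16.5 and 11), the sulfatase Arsg (24.2 against 77.7 and 67.3), the small GTPase Rab34 (7.30 against 26.7 and 18.4), Papss1, which makes the sulfate donor PAPS (2.75 against 10.97 and 12.9), and Csad (126 against 303 and 290), with adjusted p from 0.000331 to 0.0495. These genes were named after their values were seen.

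The remaining share is the part of the GF minus vendor difference, as fitted with library type as a term, that was still present 4 weeks after colonisation with TAC contents. It was 1.01 for Cyp2b10 (241 RPKM in GF_TAC), 1.09 for Cyp2c55, 0.927 for Cyp2c29, 1.005 for Raet1e, 0.905 for Arsg and 0.848 for Apoa4 (160 RPKM in GF_TAC against 538 in TAC). It lay under 0.5 for 5 genes, Csad (0.180; 265 RPKM in GF_TAC), Lsm12 (0.249), Pcgf2 (0.362), Fam89a (0.397) and Unc119 (0.482), and without the term for 12 of the 44, among them Camk1 (-0.139) and Flot1 (-0.316).

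The many genes that passed between GF and the vendors may owe much to library type. Within GF_JAX, the 2 libraries with the vendor slope minus the other 3 correlated across genes with vendor minus GF (r = 0.520). The other splits of the 10 gave at most 0.269. As these 2 were chosen by that slope, r cannot tell a technical type from a shared biological state. Library type, and the absence of microbes at sampling, were each argued against as the sole cause for 10 drug metabolism genes higher in GF, since GF_JAX 1 and GF_JAX 4, colonised and of the vendor type, kept a median share of 0.990 of the difference (quartiles 0.641 and 1.02). For the 55 genes the absence of microbes stays open, since the median remaining share in GF_TAC, 0.864 (quartiles 0.692 and 1.01), rests on the term, and without it was 0.729 over the 44 genes (quartiles 0.491 and 1.02). Untested is whether the source, housing, diet or early life of the germ-free line, or an incomplete transfer, set these genes.

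The most abundant genes fell with depth in step. At most 1 read kept per start position and strand is a candidate explanation: Alb, Apoa1 and Apoe lay at 93.5%, 92.7% and 89.0% of the 873 RPKM of JAX 1 that 2000 reads per kb would allow, and after scaling by depth their coefficient of variation was at most 2.13%. It stays open, since 9 genes with transcripts of up to 709 bases lay above that level, up to 130.9% of it (Fabp1 116.9%), which a strict limit forbids unless the authors' lengths, not given here, were shorter. True differences were argued against: before scaling the coefficient was at least 29.0%, and the genes would have had to follow inverse depth. Median slopes of log2 RPKM on log2 depth were -0.73 for 76 genes above 600 RPKM, -0.50 for 337 of 300 to 600 and 0.11 for 3285 of 5 to 20. Differences above about 300 RPKM may thus be damped, or owed to depth where, as for Hspa5, the shallower groups (TAC, GF_JAX) were higher. In some library 370 coding genes topped 0.5 of that level.

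Substrain markers mark the mice, so cecal material should not carry their difference, and the recipients serve only as a check. The recipient differences of Nnt, Wdfy1 and Entpd4 had a median ratio of -0.118 to the vendor differences, and the 95% intervals of Nnt (-0.38 to 0.12) and Wdfy1 (-0.62 to 0.27) excluded 0.5 of the vendor difference (0.46 and 0.75). That of Entpd4 (-0.43 to 0.02, against -0.42) did not, for want of precision, from which nothing is concluded.

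Counts of passing genes were compared with other splits of the same libraries, each real split included. Chance was argued against where only the real split was as large. These were TAC minus JAX (36 genes against 0 at most in 35 splits) and GF_TAC minus GF (25 against 3 in 100 drawn). GF minus JAX (2939 against 539 in 35) and GF minus TAC (2977 against 12 in 35) followed. Splits cannot tell group from library type or depth. For GF_TAC minus GF_JAX chance stays open, as 2 of 100 drawn gave as many genes, the other 110 against 21. It set GF_JAX 1, 2 and 4 and GF_TAC 2 and 5 against the rest. The fit of only these 2 groups called 0 by limma (1207 at an unadjusted p under 0.05). Nor was chance excluded for GF_JAX minus GF (11 of 100 drawn, 75 against 2859). That highest split set GF 2 and GF_JAX 1, 2 and 4 against the rest. Both splits followed the length slope (-0.0878 or more against -0.09499 or less), not the groups.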
